A study of Mus musculus with 9 samples.

How the data were processed

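RNA from 3 right atrium samples of mutants, 3 of floxed controls and 3 ventricle samples of controls was hybridised to Affymetrix mouse arrays after 3' IVT labelling, 9 arrays in all. Per the labels, the replicates are biological. The deposited values are intensity per probe set, summarised by the authors with RMA, which corrects for background and normalises between arrays by quantiles. The version and software of RMA are not stated. The values are on a linear scale, as seen from their range and from near equal quartiles in all arrays, so their log2 was taken first. No further normalisation was applied.

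Of 45101 probe sets, 64 control probe sets, 932 assigned to several genes and 9160 without a gene name were left out, which left 34945. For each gene the probe set with the highest mean over the 9 arrays was used, giving 18193 genes. Hcn4 and Ddx3y, which were to be reported, have no probe set with such a name and are not analysed here. Array spike controls for Cre say nothing about the genotype of the animals and were not used.

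All 9 arrays entered a single linear model with a mean per group, fitted with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with 6 residual and 3.48 prior degrees of freedom. The 3 comparisons were tested 2-sided with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. For 44 gene lists, written from textbook knowledge and each with at least 5 measured genes, camera was run with its preset correlation, beside camera with an estimated correlation and fry, adjusted over the lists. Counts of list members are given over all genes and adjusted over the list alone. The chamber index was tested by exact permutation, where 3 against 3 arrays cannot give a p below 0.1. The overlap of the mutant and chamber comparisons was set beside 100 simulations in which groups that do not differ share the control atria.

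The grouping, the tests, the gene lists, the alternatives except those named as added, and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold with a log2 ratio of at least 1 and no overlap between arrays, up to 4 members of each list with the smallest p, and a fixed set of heart and sex-linked genes. Genes outside it are said to be chosen after their values were seen.

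The alternatives were the replicate number as a block, an intensity trend with robust variance, leaving out the dimmest 40% of genes, quantile normalisation, median centring, the mean of all probe sets, every probe set on its own, a fit of only the 2 groups compared, array weights, a 1.5-fold minimum, an adjusted p of 0.01, the median in place of the mean over each list in the index, and leaving out each array in turn. With an array left out its group holds 2, and limma pools the spread over groups. A covariate of Y-linked genes and a covariate of hepatocyte genes were added after the data were seen. The labels do not pair the samples by number, so the model has no block.

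The procedures were tested on simulated data. Of 100 genes changed 1.5-fold, 83 were recovered, and of 100 changed 2-fold, 98, with 10 false calls (5.24% of calls). A shifted list was called and 0 others were. A simulated share of 30% ventricular signal was estimated at 29.2%. Depth does not apply to arrays, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.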

Results

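Transcript levels were measured on 9 arrays of mouse heart tissue taken at 2 months of age. The 3 groups held 3 arrays each. In the mutants, Cre recombinase under the Myh6 promoter, active in cardiomyocytes, removes the floxed gene of the nuclear receptor COUP-TFII (Nr2f2). The groups were right atria of these mutants, right atria of floxed controls without Cre, and ventricles of such controls. The median intensity per array lay between 80.9 and 83.4 and the highest between 33296 and 35272. The log2 difference between 3' and 5' control probe sets, a sign of RNA quality, varied with the groups. For Gapdh it was 0.345 to 0.364 in control atria, 0.214 to 0.304 in mutant atria and 0.153 to 0.227 in ventricles. For Actb it was 1.389 to 1.486, 1.276 to 1.383 and 1.263 to 1.367. Its effect on the comparisons was not tested. The number of arrays limits the precision of every value. Values are given on the log2 scale as mean ± SD with n = 3 arrays, and differences as log2 ratios ± SE from a limma model of all 9 arrays with 3 arrays per group. Ratios that involve a level near the array maximum, or near the background where liver transcripts lay in the ventricles (Fabp1 at 4.39 ± 0.05, Alb at 5.14 ± 0.20), are lower bounds of the difference. No gene positions are given, since the labels name no genome build.

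Arrays of the same group correlated at 0.994 to 0.996 across genes, mutant with control right atria at 0.982 to 0.989, mutant atria with ventricles at 0.978 to 0.981, and control right atria with ventricles at 0.964 to 0.971. The genes are not independent replicates, so no p is attached to these values. The first principal component held 66.1% of the variance and placed the mutant atria between both control tissues. The second held 17.8% and separated the mutant atria from both.

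The knocked-out gene was lower in the mutant atria but still detected. The probe set of Nr2f2 with the highest mean gave 6.82, 6.62 and 6.82 in the mutant atria, 7.53, 7.66 and 7.29 in the control atria and 5.96, 5.34 and 5.74 in the ventricles. The mutant mean was 6.75 ± 0.12 against 7.49 ± 0.19 in control atria and 5.68 ± 0.32 in ventricles. The mutant level was 1.67-fold lower than in control atria, a difference of -0.74 ± 0.15 (adjusted p = 0.0109), and lower in each of the 3 mutant arrays than in each control atrium. Of the other 5 probe sets of the gene, 3 fell, by between -0.77 ± 0.12 and -1.29 ± 0.13, 1 differed by -0.48 ± 0.18 (adjusted p = 0.118) and 1 by 0.14 ± 0.11 (adjusted p = 0.478). The exons that the floxed allele removes are not given, and a probe set outside them checks nothing about the deletion. With a hepatocyte covariate, chosen after the data were seen, the used probe set of Nr2f2 gave -0.44 and no longer passed (adjusted p = 0.603). That covariate nearly follows the groups and raised the median SE over genes from 0.0879 to 0.165.

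**Figure D1:**
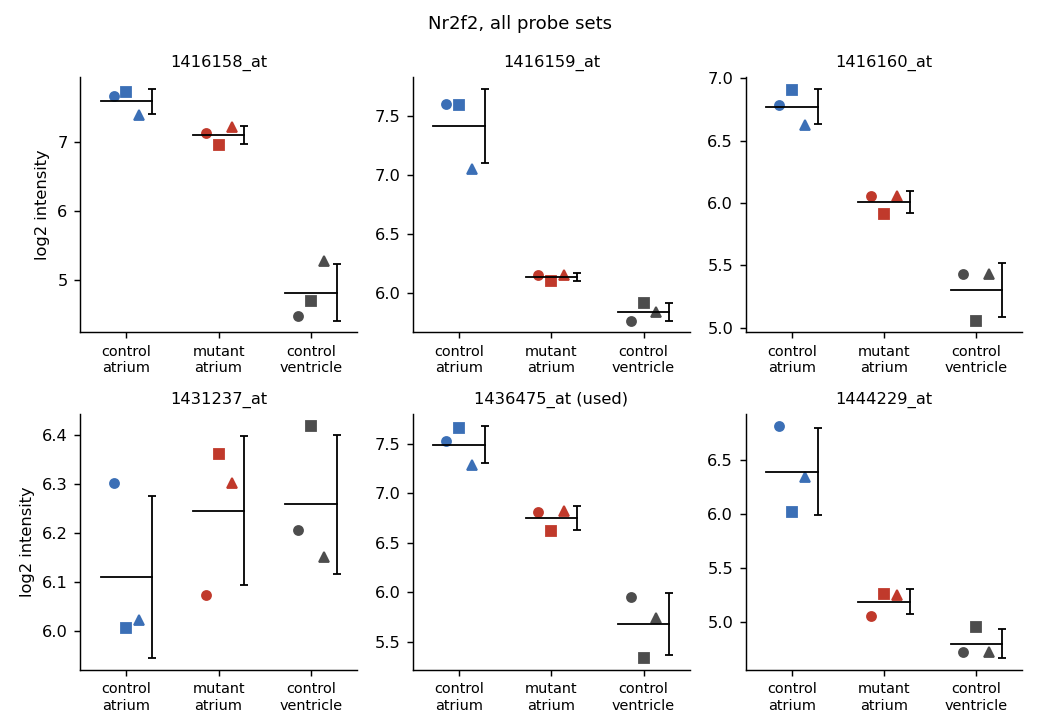
Log2 intensity of the 6 Nr2f2 probe sets in each array (points: circle, square and triangle for replicates 1, 2 and 3; line, mean; bar, SD, n = 3) for control atria in blue, mutant atria in red and ventricles in grey. In the probe set with the highest mean the mutant arrays sit near 6.75, between control atria at 7.49 and ventricles at 5.68.

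The comparison of mutant with control right atria asks which transcripts change in the atrium when COUP-TFII is removed from its cardiomyocytes. The mutants carry Cre and the controls do not, so an effect of Cre itself cannot be told apart from the removal. Several genes typical of ventricular muscle were strongly raised, while in the list of such genes 9 of 13 rose and 2 fell. Myl2, the regulatory myosin light chain of ventricular muscle, was at least 14.1-fold higher (14.86 ± 0.08 against 11.04 ± 0.58, adjusted p = 1.09e-05). The essential ventricular light chain Myl3 was 7.09-fold higher (adjusted p = 4.11e-07), the slow myosin heavy chain Myh7 12-fold (3.58 ± 0.22) and the transcription factor Irx3, present in the fast conduction system, 11-fold (3.46 ± 0.15). The largest rise was that of Thbs4, a secreted matrix protein, which was 36.2-fold higher (12.10 ± 0.34 against 6.93 ± 0.05). The next were Cenpf, a kinetochore gene (26.5-fold, 10.78 ± 0.03 against 6.05 ± 0.28), and Kcne1l (22.8-fold, 4.51 ± 0.78). The fibrillin Fbn2 rose 20.6-fold, the axon guidance ligand Slit2 17.2-fold, Mpped2 16.5-fold and Tesc 13.1-fold.

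The atrial genes responded unevenly. Dkk3, a secreted protein abundant in atria, fell by 1.37 ± 0.12 (adjusted p = 0.000124), Tbx5, a transcription factor of the atria, by -0.86 ± 0.09 and Nr2f1, the close relative of the removed gene, was 2-fold lower (log2 SE 0.17). The gap junction gene Gja5 fell by 1.09 ± 0.16, to a level near background, and Sln, the atrial regulator of the calcium pump, by 1.75 ± 0.50 (adjusted p = 0.0398). The atrial light chains differed by -1.35 ± 0.57 for Myl7 (adjusted p = 0.136) and -0.49 ± 0.49 for Myl4 (adjusted p = 0.526), without passing. Myl4 did pass with the mean of all probe sets (-1.10, adjusted p = 0.0233), and both passed in fits of only the mutant and control atria (0.04 for Myl7 and 0.0222 for Myl4). Nppa, the atrial natriuretic peptide, stood at 15.07 ± 0.02 in mutant and 15.10 ± 0.01 in control atria, and Myh6, whose promoter drives the Cre, at 14.95 ± 0.01 and 14.97 ± 0.02. These last 4 genes, like Myl2 and Myl3 in the ventricle, lie near the top of the intensity range, where differences are compressed and equal levels cannot be read as equal amounts.

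In all, 3192 of 18193 genes changed (17.5%), of which 1411 rose and 1781 fell (1491 and 1432 with quantile normalisation), with a median absolute log2 difference of 0.43. At least 2-fold differences were found for 162 risen and 242 fallen genes. Among the largest falls were 5 liver transcripts, Serpina1c (-5.99 ± 0.53), Alb (-5.65 ± 0.68), Serpina1b (-4.54), Ttr (-4.50 ± 0.42) and Fabp1 (-3.78 ± 0.81). They were low in mutant atria, as for Alb at 4.95 ± 0.27, and varied between the control atria, where Alb stood at 10.60 ± 1.77. Other large falls were of Gadl1, a decarboxylase (at least 17.5-fold lower, with mutant atria near background at 4.80 ± 0.16), and of Hamp, which encodes hepcidin (16.9-fold lower). Hamp had similar levels in the control atria (12.45 ± 0.16).

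The count rests on few arrays: without 1 array it was 1832 (mutant replicate 2), 1990 (mutant replicate 3), 1972 (control atrium replicate 1) or 2013 (control atrium replicate 2), and 246 with the hepatocyte covariate, under which Thbs4, Slit2, Myl2, Myl3, Irx3 and Dkk3 passed. Under it Tbx5 (-0.78, adjusted p = 0.0969), Nr2f1 (-0.81, 0.343), Gja5 (-0.44, 0.4), Sln (-1.60, 0.587), Irx4 (0.75, 0.586) and Kcne1l did not pass, and over all comparisons 170 of 699 results lost their call. In mutant against control atria the covariate raised the median SE from 0.0879 to 0.165, while 98.1% of the genes called without it kept their sign. Calls also changed for Irx4 (adjusted p = 0.0615 without mutant replicate 2, 0.0705 without mutant replicate 3 and 0.0769 without control atrium replicate 1), Sln (0.0829 without mutant replicate 1, 0.129 without mutant replicate 2, 0.0772 to 0.103 without a control atrium, 0.0958 with an intensity trend and 0.0531 with the Y-linked covariate) and Myl7 (0.0241 without ventricle replicate 1).

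Of the 44 gene lists, camera with its preset correlation called 15, of which 12 were higher and 3 lower in the mutant atria. None passed with an estimated correlation, where the smallest adjusted p was 0.335, while fry, which tests whether a list's genes move on balance one way, called 17. In the ventricular muscle list 9 of 13 measured genes rose and 2 fell, the same counts as adjusted over the list alone (median 1.27, adjusted p = 5.86e-06, and adjusted p = 0.335 with an estimated correlation). Fhl2, a LIM protein of the heart, rose by 1.27 ± 0.06. The repressor Hey2 lay near background in all groups and passed as a fall in the mutant atria. Its call was lost without control atrium replicate 2 (-0.51, adjusted p = 0.0517) and with the hepatocyte covariate (-0.83, adjusted p = 0.163). Irx4, the ventricular homeobox factor, rose by 0.98 ± 0.24, to 5.94 ± 0.56 against 8.96 ± 0.18 in ventricles. In the atrial muscle list 10 of 16 fell and 1 rose, as over the list alone (median -0.85, adjusted p = 1.79e-06, and adjusted p = 0.452 with an estimated correlation). Its members include Dkk3, Tbx5 and the potassium channel gene Kcnj5 (-0.83 ± 0.10).

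In the list of the Purkinje fibres and ventricular conduction system 6 of 8 genes rose, or 8 of 8 adjusted over the list alone (median 1.01, adjusted p = 5.44e-06, and adjusted p = 0.335 with an estimated correlation). Besides Slit2, the guidance cue Sema3a rose by 2.00 ± 0.17, the cell adhesion gene Cntn2 by 1.57 ± 0.24 and the potassium channel subunit Kcne1 by 0.98 ± 0.14. In control ventricles against control atria 2 of the 8 genes were higher and 3 lower, with a median of -0.22. Camera did not call the list there (adjusted p = 0.863), so as a whole it did not set the control tissues apart. All 13 epicardial and mesothelial markers fell, also over the list alone (median -1.49, adjusted p = 3.47e-12, and adjusted p = 0.335 with an estimated correlation). Bnc1, a transcription factor of mesothelium, fell by 2.02 ± 0.12, the uroplakin Upk3b by 1.75 ± 0.17, and the keratins Krt19 by 1.64 ± 0.15 and Krt18 by 1.49 ± 0.14. The control atria in which these markers were higher also held the liver transcripts.

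Most energy metabolism genes that passed rose. For fatty acid oxidation 13 of 22 genes rose and none fell (15 over the list alone, median 0.33, adjusted p = 5.44e-06, and adjusted p = 0.555 with an estimated correlation), led by Ech1 (0.68 ± 0.12), Eci1 (0.64 ± 0.08) and Hadha (0.59 ± 0.09). For oxidative phosphorylation 10 of 43 rose and 1 fell (14 and 1 over the list alone, median 0.13, adjusted p = 2.38e-05, and adjusted p = 0.555 with an estimated correlation). Sdhd rose by 0.44 ± 0.07 and Cox7c fell by 0.53 ± 0.10. In the tricarboxylic acid cycle 5 of 19 rose (6 over the list alone, adjusted p = 0.000383, and adjusted p = 0.555 with an estimated correlation), among them Idh2 (0.65 ± 0.08) and the citrate synthase gene Cs (0.46 ± 0.07). In glycolysis 7 of 16 rose and 2 fell (8 and 2 over the list alone, adjusted p = 0.0168, and adjusted p = 0.561 with an estimated correlation), with the hexokinase Hk1 at 0.81 ± 0.07 and the glucose transporter Slc2a1 at -0.47 ± 0.08. Creatine and muscle energy genes rose in 5 of 11 cases and fell in 1 (6 and 1 over the list alone, adjusted p = 0.0173, and adjusted p = 0.555 with an estimated correlation), with the mitochondrial creatine kinase Ckmt2 at 0.75 ± 0.09.

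Markers of other cell types also differed. Macrophage and myeloid markers rose in 8 of 16 cases (9 over the list alone, median 0.44, adjusted p = 0.000414, and adjusted p = 0.561 with an estimated correlation), with the lysosomal protein Cd68 at 0.79 ± 0.14. Smooth muscle and pericyte markers rose in 6 of 14 cases and fell in 1 (8 and 1 over the list alone, adjusted p = 0.00536, and adjusted p = 0.555 with an estimated correlation). The potassium channel regulator Abcc9 rose by 1.52 ± 0.13 and the pericyte proteoglycan Cspg4 by 0.92 ± 0.09, while Cnn1, which encodes smooth muscle calponin, fell by 3.38 ± 0.18. Extracellular matrix genes rose in 6 of 24 cases and fell in 1, as over the list alone (adjusted p = 0.00327, and adjusted p = 0.561 with an estimated correlation). Among them the microfibril protein Mfap4 rose by 1.56 ± 0.12 and Mfap5 by 0.55 ± 0.07. In the fibroblast list 3 of 14 rose, as over the list alone (adjusted p = 0.0274, and adjusted p = 0.555 with an estimated correlation), including Thy1 (0.69 ± 0.10). In the cell cycle list 5 of 21 rose (6 over the list alone, adjusted p = 0.0413, and adjusted p = 0.555 with an estimated correlation), including the proliferation marker Mki67 (0.61 ± 0.10). In the heat shock and unfolded protein list 2 of 16 fell, as over the list alone (adjusted p = 0.0168, and adjusted p = 0.561 with an estimated correlation), the chaperone Dnajb9 by -0.57 ± 0.08 and the stress factor Xbp1 by -0.41 ± 0.07. The matrix list did not pass without mutant replicate 2 (adjusted p = 0.0634) and the fibroblast list without mutant replicate 2 (0.0762) or control atrium replicate 2 (0.0757). The heat shock list did not pass without mutant replicate 1 (0.0747) or control atrium replicate 3 (0.138), nor the cell cycle list without mutant replicate 1 (0.0516), mutant replicate 2 (0.0882), control atrium replicate 1 (0.0579) or control atrium replicate 2 (0.0708). The cell cycle list also failed with the replicate block (adjusted p = 0.0545), quantile normalisation (0.0528), the mean of all probe sets (0.0503), the Y-linked covariate (0.0503) and without the dimmest 40% of genes (0.427), and the heat shock list without the dimmest genes (0.134) and with array weights (0.114). With the hepatocyte covariate the glycolysis (adjusted p = 0.293), creatine (0.448), matrix (0.448), fibroblast (0.166) and cell cycle (0.448) lists did not pass either, nor did several of the genes named, such as Hadha, Cs, Ckmt2, Cd68, Thy1 and Mki67.

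**Figure D2:**
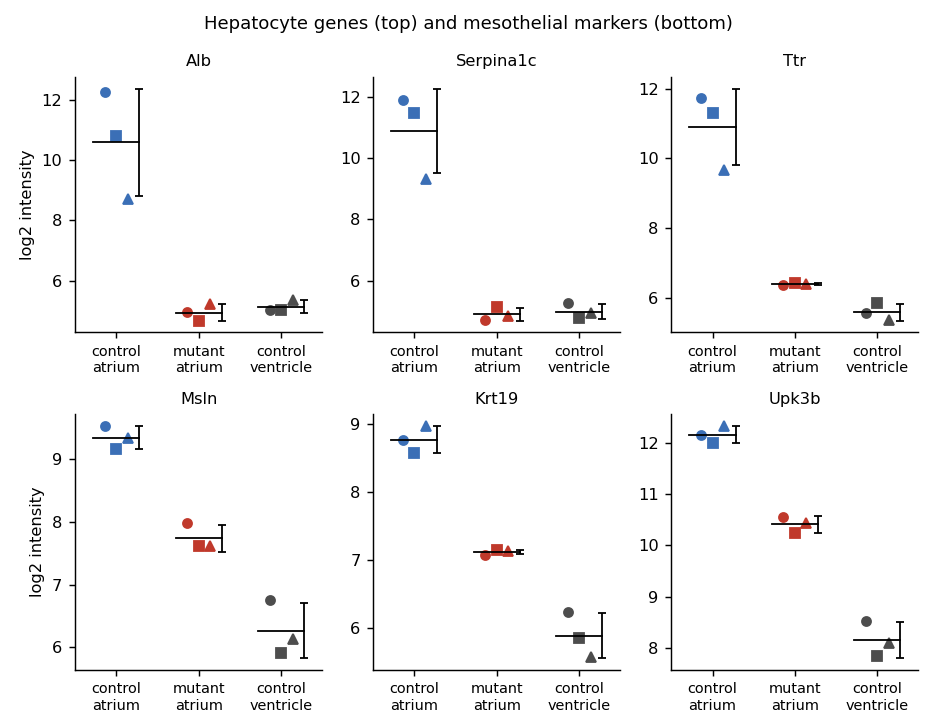
Log2 intensity per array of the liver transcripts Alb, Serpina1c and Ttr (upper panels) and the mesothelial markers Msln (chosen after its values were seen), Krt19 and Upk3b (lower panels), with points for replicates 1 (circle), 2 (square) and 3 (triangle), lines for means and bars for SD (n = 3). The liver transcripts spread widely between the control atria, with an SD of 1.77 for Alb, while the SD of Krt19 there was 0.20 and that of Upk3b 0.17.

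The comparison of control ventricle with control right atrium shows how both chambers differ without the mutation. The ventricle had far less of the atrial muscle genes. Dkk3 was 122.9-fold lower (-6.94 ± 0.12). The atrial level of Sln, Myl7, Myl4 and Nppa lies near the top of the range, so their folds are lower bounds: at least 588-fold for Sln (-9.20 ± 0.50), 264.5-fold for Myl7 (-8.05 ± 0.57), 118.3-fold for Myl4 (-6.89 ± 0.49) and 4.91-fold for Nppa. The ventricle had more Timp4, an inhibitor of matrix proteases (24.3-fold, 4.60 ± 0.24), skeletal actin Acta1 (4.50 ± 0.56), Lrtm1 (21.5-fold), Irx4 (16.1-fold, 4.01 ± 0.24), Myl2 (at least 15.6-fold, 3.96 ± 0.23) and Myl3 (at least 8.78-fold). Each of these changes passed at an adjusted p of at most 0.000144, the value for Acta1.

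In all, 9615 of 18193 genes differed (52.8%), with 5314 higher and 4301 lower in the ventricle, and 420 and 878 by at least 2-fold. Without the dimmest 40% of genes the balance turned, with 2931 higher and 3881 lower, as it did with a 1.5-fold minimum (1286 and 1879). With the hepatocyte covariate 2776 differed, 1294 higher and 1482 lower. All 3 ventricles had high Xist and low Y-linked transcripts, while the control atria were mixed, and with a Y-linked covariate, chosen after the data were seen, 7415 genes differed.

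Camera called 18 lists, 7 higher and 11 lower in the ventricle, against 27 by fry and 0 with an estimated correlation (smallest adjusted p 0.217). Of the atrial muscle list 15 of 16 were lower and 1 higher, as over the list alone (median -2.84, adjusted p = 6.53e-11, and adjusted p = 0.217 with an estimated correlation). Of the ventricular muscle list 10 of 13 were higher, as over the list alone (median 1.62, adjusted p = 2.85e-05, and adjusted p = 0.266 with an estimated correlation). All 13 mesothelial markers were lower, also over the list alone (median -2.81, adjusted p = 8.46e-11, and adjusted p = 0.217 with an estimated correlation), led by Upk3b (-4.01 ± 0.17), and the liver transcripts were lower with them, as was Alb by -5.45 ± 0.68.

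Mitochondrial genes were higher in the ventricle. This held for 36 of 43 oxidative phosphorylation genes, with 1 lower (37 and 1 over the list alone, adjusted p = 4.13e-08, and adjusted p = 0.348 with an estimated correlation). It held for 19 of 22 fatty acid oxidation genes with 1 lower, as over the list alone (adjusted p = 8.14e-08, and adjusted p = 0.289 with an estimated correlation). It also held for 18 of 19 tricarboxylic acid cycle genes, as over the list alone (adjusted p = 7.35e-07, and adjusted p = 0.348 with an estimated correlation). Eci1 was higher by 1.67 ± 0.08, Suclg2 by 1.25 ± 0.07 and Cox8b by 0.67 ± 0.06. Glycolysis genes were higher in 11 of 16 cases and lower in 2, as over the list alone (adjusted p = 0.013, and adjusted p = 0.581 with an estimated correlation), with the hexokinase Hk2 at 1.18 ± 0.08. Creatine and muscle energy genes were higher in 8 of 11, as over the list alone (adjusted p = 0.0109, and adjusted p = 0.505 with an estimated correlation). Smooth muscle and pericyte markers were higher in 11 of 14 with 2 lower (12 and 2 over the list alone, adjusted p = 0.0049, and adjusted p = 0.391 with an estimated correlation), with the pericyte gene Rgs5 at 2.05 ± 0.14.

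Genes of the BMP and TGF-beta pathway were lower in 13 of 18 cases and higher in 2 (14 and 2 over the list alone, adjusted p = 4.62e-05, and adjusted p = 0.217 with an estimated correlation), with the BMP targets Id2 at -3.01 ± 0.12 and Smad6 at -2.35 ± 0.13. Extracellular matrix genes were lower in 16 of 24 and higher in 1, as over the list alone (adjusted p = 8.03e-05, and adjusted p = 0.505 with an estimated correlation). Fibroblast markers were lower in 10 of 14 with 1 higher (10 and 2 over the list alone, adjusted p = 0.00299, and adjusted p = 0.348 with an estimated correlation). Endocardial and endothelial markers were lower in 9 of 15 and higher in 2 (9 and 3 over the list alone, adjusted p = 0.00378, and adjusted p = 0.289 with an estimated correlation). Among them were Npr3, a marker of endocardium (-4.32 ± 0.16), and Plvap, a protein of vessel fenestrae (-3.77 ± 0.15). Wnt pathway genes were lower in 9 of 18 and higher in 2, as over the list alone (adjusted p = 0.0108, and adjusted p = 0.289 with an estimated correlation). Circadian clock genes were lower in 9 of 15, as over the list alone (adjusted p = 0.00311, and adjusted p = 0.217 with an estimated correlation). Ribosomal protein genes were lower in 9 of 14 (10 over the list alone, adjusted p = 0.00311, and adjusted p = 0.581 with an estimated correlation). Macrophage markers were lower in 8 of 16, as over the list alone (adjusted p = 0.00498, and adjusted p = 0.652 with an estimated correlation). Heat shock genes were lower in 8 of 16 and higher in 1 (8 and 2 over the list alone, adjusted p = 0.0123, and adjusted p = 0.581 with an estimated correlation), without passing when control atrium replicate 3 was left out (adjusted p = 0.0544). With the Y-linked covariate the macrophage (adjusted p = 0.151) and heat shock (0.115) lists did not pass, without the dimmest 40% of genes the endothelial (0.0603), macrophage (0.0602) and heat shock (0.131) lists did not, and with the hepatocyte covariate the ribosomal list (0.0834) did not.

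The comparison of mutant right atrium with control ventricle asks how far the mutant atria lie from ventricular tissue. Many atrial muscle genes stood far above their ventricular level. Sln was at least 175-fold higher than in the ventricle (7.45 ± 0.50), Myl7 103.6-fold (6.70 ± 0.57), Myl4 84.3-fold (6.40 ± 0.49) and Dkk3 47.6-fold (5.57 ± 0.12). The light chain Myl2 stood at 14.86 ± 0.08 against 15.01 ± 0.01 in the ventricle, both near the array maximum, where differences are compressed. Myh7 was 2-fold above the ventricle (12.08 ± 0.14 against 11.08 ± 0.54, adjusted p = 0.00628). Other ventricular genes stayed far below the ventricle, among them Lrtm1 (-4.68 ± 0.12), Myot, a protein of the Z-disc (-3.42 ± 0.43), Timp4 (-3.40 ± 0.24) and Irx4 (-3.02 ± 0.24). The 8 genes with the largest deficit also held Bex1, at -4.49 ± 0.23.

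In all, 5956 of 18193 genes differed (32.7%), with 2910 higher and 3046 lower in the mutant atria, and 619 and 196 by at least 2-fold. This balance depends on the settings, with 2766 higher and 2438 lower without the dimmest 40% of genes, 2338 and 2110 with the Y-linked covariate, 2670 and 3602 with median centring and 2657 and 3436 with quantile normalisation. Camera called 20 lists, 15 higher and 5 lower, against 29 by fry and 0 with an estimated correlation (smallest adjusted p 0.218). The atrial muscle list was higher in 15 of 16 genes and lower in 1, as over the list alone (median 2.19, adjusted p = 3.28e-12, and adjusted p = 0.218 with an estimated correlation). The ventricular muscle list was lower in 6 of 13 and higher in 2, as over the list alone (median -0.31), and was not called (adjusted p = 0.0949, and adjusted p = 0.485 with an estimated correlation). Without mutant replicate 2 it was (adjusted p = 0.0291).

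Lists higher in the mutant atria than in the ventricle also covered connective and other non-muscle cells and the conduction system. Extracellular matrix genes were higher in 16 of 24, as over the list alone (adjusted p = 5.24e-10, and adjusted p = 0.232 with an estimated correlation), with Mfap4 at 2.12 ± 0.12. Mesothelial markers were higher in 13 of 13, also over the list alone (adjusted p = 6.98e-09, and adjusted p = 0.218 with an estimated correlation). So were macrophage markers in 14 of 16 (15 over the list alone, adjusted p = 3.48e-08, and adjusted p = 0.304 with an estimated correlation) and fibroblast markers in 10 of 14 with 2 lower, as over the list alone (adjusted p = 5.5e-06, and adjusted p = 0.232 with an estimated correlation). Endothelial markers were higher in 7 of 15 and lower in 1 (7 and 2 over the list alone, adjusted p = 0.00518, and adjusted p = 0.232 with an estimated correlation). BMP and TGF-beta genes were higher in 11 of 18 and lower in 1 (12 and 1 over the list alone, adjusted p = 1.64e-06, and adjusted p = 0.218 with an estimated correlation), with Id2 at 2.75 ± 0.12 and the ligand Bmp6 at 1.52 ± 0.10. Sinus node and pacemaker genes were higher in 8 of 13 and lower in 1, as over the list alone (adjusted p = 0.00156, and adjusted p = 0.218 with an estimated correlation), with the calcium channel Cacna1h at 3.54 ± 0.24 and the transcription factor Shox2 at 1.76 ± 0.15. Purkinje genes were higher in 4 of 8 and lower in 1 (5 and 1 over the list alone, adjusted p = 0.00641, and adjusted p = 0.298 with an estimated correlation), with Slit2 at 4.53 ± 0.14.

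Mitochondrial genes were lower in the mutant atria than in the ventricle. For fatty acid oxidation this held in 18 of 22 cases, with 1 higher (20 and 1 over the list alone, adjusted p = 1.91e-07, and adjusted p = 0.232 with an estimated correlation). It held in 23 of 43 for oxidative phosphorylation (29 over the list alone, adjusted p = 9.73e-07, and adjusted p = 0.304 with an estimated correlation) and in 15 of 19 for the tricarboxylic acid cycle, as over the list alone (adjusted p = 3.3e-06, and adjusted p = 0.304 with an estimated correlation). Eci1 differed by -1.03 ± 0.08 and Suclg2 by -0.94 ± 0.07. Of the other 8 called lists, the Wnt list was higher in 7 of 18 genes and lower in 1 (8 and 1 over the list alone, adjusted p = 0.00814, and adjusted p = 0.232 with an estimated correlation). The circadian list was higher in 7 of 15 and lower in 1 (9 and 2 over the list alone, adjusted p = 0.0166, and adjusted p = 0.232 with an estimated correlation). The smooth muscle list was higher in 1 and lower in 7 of 14 genes (1 and 8 over the list alone, adjusted p = 0.0348, and adjusted p = 0.469 with an estimated correlation), and the cardiac stress list higher in 5 and lower in 2 of 13, as over the list alone (adjusted p = 0.0348, and adjusted p = 0.298 with an estimated correlation). The ribosomal list was higher in 5 of 14, as over the list alone (adjusted p = 0.0316, and adjusted p = 0.573 with an estimated correlation). The adrenergic list was higher in 7 and lower in 3 of 14, as over the list alone (adjusted p = 0.0434, and adjusted p = 0.232 with an estimated correlation). The creatine list was higher in 1 and lower in 5 of 11 (1 and 6 over the list alone, adjusted p = 0.0457, and adjusted p = 0.485 with an estimated correlation), and the interferon list higher in 2 and lower in 1 of 15, as over the list alone (adjusted p = 0.0464, and adjusted p = 0.622 with an estimated correlation). Each of these last 6 lost its call without certain arrays. For smooth muscle this was ventricle replicate 3 (adjusted p = 0.0919), for stress ventricle replicate 2 (0.0638) and for the ribosomal list mutant replicate 1 (0.153) and ventricle replicates 1 (0.0549) and 3 (0.0542). For the adrenergic list they were mutant replicates 1 (0.0512) and 2 (0.0715) and ventricle replicate 1 (0.0715), for the creatine list mutant replicates 1 (0.0766) and 3 (0.0591) and each ventricle replicate (0.0542 to 0.0699), and for the interferon list mutant replicate 2 (0.268) and ventricle replicates 2 (0.118) and 3 (0.135). Other alternatives ended calls too. Without the dimmest 40% of genes these were the circadian (adjusted p = 0.0589), stress (0.122), ribosomal (0.1) and interferon (0.243) lists, and with the Y-linked covariate the stress (0.0812) and interferon (0.416) lists. With the mean of all probe sets they were the smooth muscle (0.0763), adrenergic (0.0787) and creatine (0.0699) lists, with array weights the smooth muscle (0.0587), adrenergic (0.0581) and ribosomal (0.064) lists, and with quantile normalisation the creatine (0.0563) and interferon (0.0745) lists.

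A chamber index, the mean of the 13 ventricular genes minus that of the 16 atrial genes, placed the mutant atria between the tissues. It was -3.27 ± 0.07 in control atria, -0.94 ± 0.45 in mutant atria and 2.35 ± 0.23 in ventricles (SD, n = 3). The mutant arrays gave -1.16, -0.43 and -1.24, so that no group overlapped another. The mutant atria lay 2.33 above control atria and differed by -3.29 from ventricles, and the ventricles lay 5.62 above control atria. Each 2-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The index covered 41.4% of the distance between the control tissues. The ventricular list, with Myl2 and Myl3, covered 76.7% and the atrial list, with Sln and Myl7, 25.1%. Both lists hold genes near the array maximum, such as Myl2 in ventricles and Nppa in atria, so compression enters these shares. With medians in place of means the mutant atria lay 3.81 above control atria and differed by -2.99 from ventricles, which lay 6.81 above control atria.

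**Figure D3:**
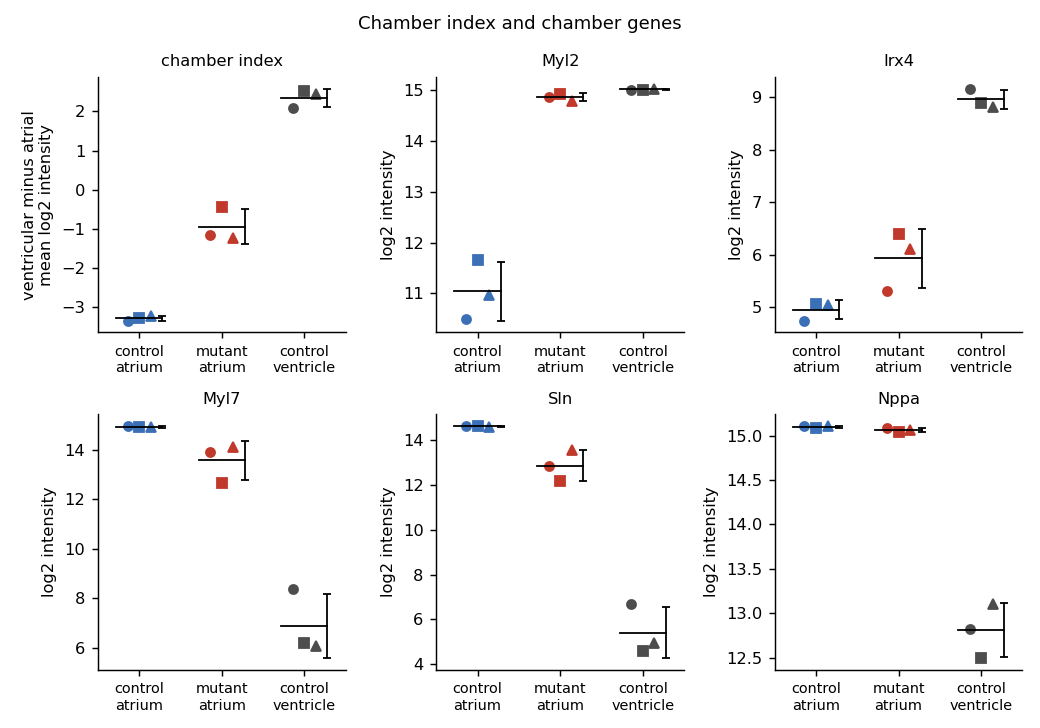
Chamber index and log2 intensity of Myl2, Irx4, Myl7, Sln and Nppa per array in control atria (blue), mutant atria (red) and ventricles (grey), with circles, squares and triangles for replicates 1, 2 and 3, lines for means and bars for SD (n = 3). Irx4 in the mutant atria (5.94) lies nearer to control atria (4.95) than to ventricles (8.96), while Myl2 in mutant atria and ventricles and Nppa in both atria lie near the array maximum.

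The genes that changed in the mutant atria were compared with those that set the control ventricle apart from the control atrium. Of the 9615 chamber genes, 2460 (25.6%) changed in the mutant atria in the ventricular direction, 1015 upward, as did Myl2, Tesc and Mpped2, and 1445 downward, as did Dkk3, Gadl1 and Bnc1. A further 177 moved the opposite way, as did Slit2 and Sema3a, which rose in the mutant atria and were lower in the ventricle than in the control atrium. Independent lists of the same sizes would share 833.2 and 853.8 genes, but both comparisons use the same control atria, so these values are no baseline. Of the 420 genes at least 2-fold higher in the ventricle 263 rose in the mutant atria (62.6%), and of the 878 at least 2-fold lower 477 fell (54.3%). The downward counts include liver transcripts found in the control atria, such as Alb. Of 47 measured, 33 were lower in ventricles and 31 lower in mutant atria than in control atria. All 13 mesothelial markers, Bnc1 among them, were lower in both. How far these genes raise the counts and the correlation was not tested.

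Both comparisons use the same 3 control atria, which are too few to be split. In 100 simulations of unchanged groups against shared controls the mean correlation of the log2 ratios was 0.5, at most 0.541, against 0.645 across genes in the data, and the covariance was 0.00701 against 0.158, a difference of 0.151. The simulations shared 0.03 called genes on average. They held no chamber difference, and on average 0.12 chamber and 0.08 mutant genes were called in them. They therefore give no baseline for the overlap count or the correlation. Without 1 array the count moving the same way was 1436 (mutant replicate 2), 1544 (mutant replicate 3), 1501 (control atrium replicate 1) or 1615 (control atrium replicate 2), and the opposite count 109, 95 and 83 without the last 3 of these and 112 without control atrium replicate 3. With the hepatocyte covariate the counts were 195 and 5.

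**Figure D4:**
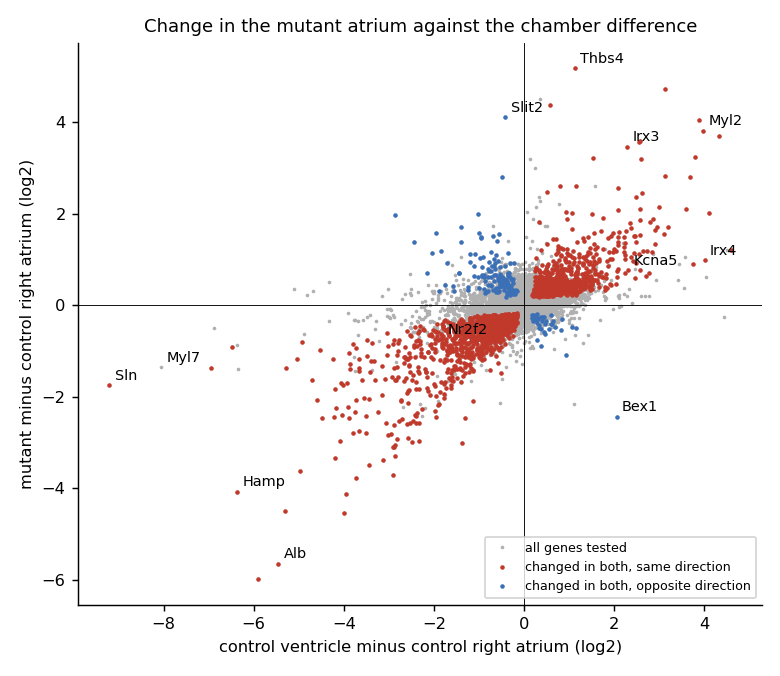
Log2 ratio of mutant to control right atrium (y axis) against log2 ratio of control ventricle to control right atrium (x axis), a point per gene, with all genes in grey, genes called in both comparisons with the same direction in red and with opposite directions in blue. Red points number 2460 and blue points 177, and both axes share the control atria.

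Some genes lay outside the range of both control tissues. In the mutant atria 364 genes were above and 239 below both, 52 and 7 by at least 2-fold. Independent lists would share 226 and 298, but both comparisons use the same mutant arrays and the control tissues differ from each other. The simulations gave 0 on average, but almost no gene was called in them. Neither the independent lists nor the simulations therefore give a baseline. Thbs4 exceeded control atria by 5.18 ± 0.15 and ventricles by 4.06 ± 0.15, Slit2 by 4.11 ± 0.14 and 4.53 ± 0.14, and Fbn2 by 4.37 ± 0.18 and 3.79 ± 0.18. The Iroquois factors Irx3 and Irx5 exceeded the ventricle by 1.18 ± 0.15 and 1.44 ± 0.21. Kcne1l, a potassium channel subunit, was above both by 4.51 ± 0.78 and 4.17 ± 0.78 and varied between the mutant arrays (SD 2.06). Bex1 was below both, by -2.44 ± 0.23 and -4.49 ± 0.23. Another 1059 genes lay between the control tissues and differed from both, as did Dkk3 and Nr2f1.

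**Figure D5:**
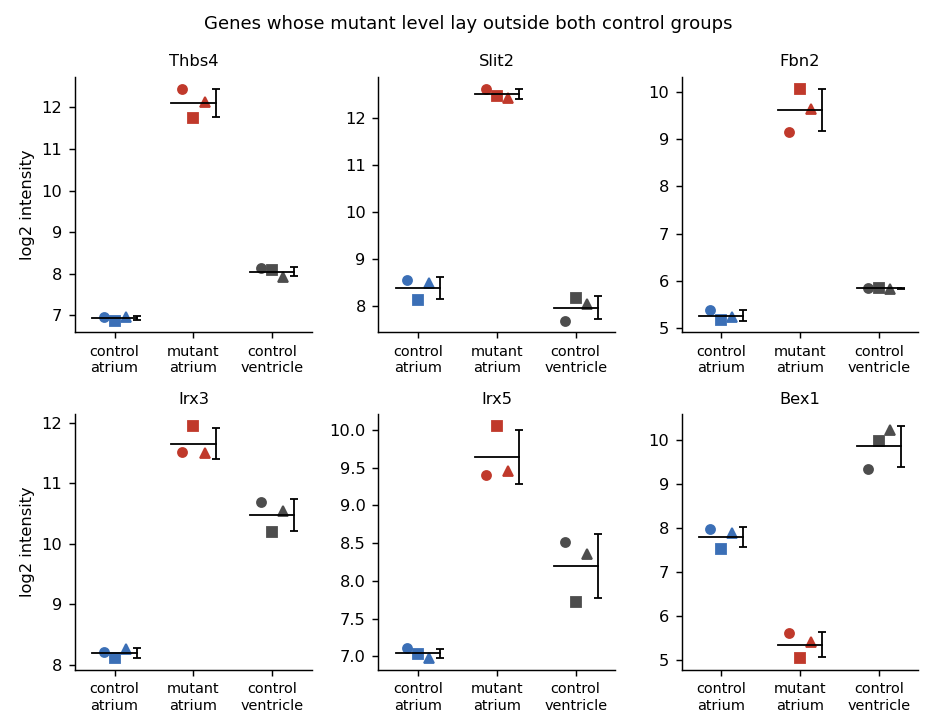
Log2 intensity per array of Thbs4, Slit2, Fbn2, Irx3, Irx5 and Bex1 in control atria (blue), mutant atria (red) and ventricles (grey), with circles, squares and triangles for replicates 1, 2 and 3, lines for means and bars for SD (n = 3). The mutant atria lie above both control tissues for the first 5 genes, as for Thbs4 at 12.10 against 6.93 and 8.05, and below both for Bex1.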

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

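The covariates were added after the data were seen and the other alternatives before. Results that passed in neither fit aside, those that turned sign under any alternative or without any array were Asph (0.051 in mutant against control atria) and Egr3 (-0.11 in ventricle against control atria and 0.19 in mutant atria against ventricle) with the mean of all probe sets, where the probe sets of each gene gave opposite signs. The others were Uty (0.39 in ventricle against control atria and -0.33 in mutant atria against ventricle) and Xist (-2.86 in ventricle against control atria) with the Y-linked covariate, and Fabp1 (0.39 in mutant against control atria) with the hepatocyte covariate, which removes what these genes share. Counts moved by construction where the threshold or the features changed. Every probe set tested gave 5144, 20054 and 10993 in the 3 comparisons in the order of the report and 4003 in the overlap of the same direction. A 1.5-fold minimum gave 984, 3165 and 2080, with 701 and 48 in the overlap of the same and the opposite direction. An adjusted p of 0.01 gave 1267 for mutant against control atria and 3648 for mutant atria against ventricle, with 982 and 52 in the overlap.

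The hepatocyte covariate gave 246 and 2776 genes in the comparisons with control atria and 195 and 5 in the overlap, and Nr2f2 -0.44 (adjusted p = 0.603; 0.000581 to 0.0445 under the other alternatives). The covariate nearly follows the groups, so the median SE rose from 0.0879 to 0.165, while the median absolute log2 ratio of the called genes went from 0.43 to 0.408 and 98.1% kept their sign. With both fits 234 genes were called.

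With an estimated correlation 0 lists were called in each comparison, including the atrial list with mean shifts of -0.96, -3.84 and 2.88 and the ventricular list with 1.37 and 1.78. In mutant atria against ventricle the ventricular list passed with fry (-0.41, adjusted p = 0.00495) and with the Y-linked covariate (-0.54, adjusted p = 0.0244), against 0.0291 to 0.485 under the other alternatives. The index differences between ventricle and control atria and between mutant atria and ventricle became 5.17 and -2.85 with the mean of all probe sets. With medians they were 6.81 and -2.99, and 3.81 between mutant and control atria. The cause was not tested.

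Without 1 array the counts ranged from 1832 to 3074 for mutant against control atria, 7742 to 9459 for ventricle against control atria and 4657 to 5961 for mutant atria against ventricle, the overlap from 1436 to 2361 and 83 to 178, and Nr2f2 from -0.84 to -0.66. List calls ranged from 13 to 16, 17 to 19 and 16 to 21. The mean shift of the atrial list ranged from -1.09 to -0.80, -3.98 to -3.73 and 2.75 to 3.04, that of the ventricular list from 1.27 to 1.44, 1.75 to 1.81 and -0.51 to -0.34. The index differences ranged from 2.07 to 2.48, 5.54 to 5.75 and -3.55 to -3.14. The arrays that moved a count by over 1.5 times were mutant replicates 2 (1832) and 3 (1990) and control atria 1 (1972) and 2 (2013), which are counts for mutant against control atria, and control atrium 3 for the overlap of the opposite direction (112). The replicate number as a block gave 2704, 9199 and 5573 genes. Signal near background limits dim genes, and the split of 5314 higher and 4301 lower genes in the ventricle became 2931 and 3881 without the dimmest 40%.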

Other observations

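Both tests of ventricular tissue in the mutant samples were chosen after the results were seen, the second after the first and with the spread of the shares known, the Y-linked covariate and the hepatocyte list were added after the data were seen, and the other tests were written before their results.

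Several lists that camera did not call in mutant against control right atria held strong changes in opposite directions. In the sinus node list (4 of 13 rose, 4 fell, adjusted p = 0.935; 4 and 5 over the list alone) the connexin Gjc1 rose by 1.21 ± 0.08 and the T-type calcium channel Cacna1g by 0.70 ± 0.12, while Cpne5 fell by 2.09 ± 0.17. In the Wnt list (3 of 18 rose, 6 fell, adjusted p = 0.298; 4 and 6 over the list alone) the secreted inhibitor Wif1 rose by 2.45 ± 0.38, while the inhibitor Sfrp5 fell by 2.53 ± 0.20 and Axin2, a target of the pathway, by 0.97 ± 0.09. In the BMP and TGF-beta list (3 of 18 rose, 3 fell, adjusted p = 0.668; 4 and 4 over the list alone) the ligand Bmp5 fell by 1.68 ± 0.20. In the retinoic acid list (1 of 16 rose, 3 fell, as over the list alone, adjusted p = 0.758) the receptor Rxrg rose by 0.45 ± 0.08, and Rbp4, which liver also makes in quantity, fell by 2.42 ± 0.37. Of the transcription factors of the heart (3 of 15 rose, 2 fell, adjusted p = 0.578; 5 and 2 over the list alone) Hopx rose by 0.61 ± 0.07 and Hand2 by 0.58 ± 0.12.

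Other lists without a call also held changed genes. Among adipocyte markers (3 of 12 rose, 3 fell, as over the list alone, adjusted p = 0.578) Cidea, a gene of lipid droplets, rose by 1.14 ± 0.16, while the desaturase Scd1 fell by 1.32 ± 0.15 and Car3 by 3.71 ± 0.61. Among neuron and Schwann cell markers (2 of 15 rose, 1 fell, as over the list alone, adjusted p = 0.142) Uchl1 rose by 1.89 ± 0.19 and the myelin gene Mbp fell by 1.02 ± 0.12. Of the circadian clock genes 4 of 15 fell, as over the list alone (adjusted p = 0.0575, and 0.0474, 0.048 and 0.0361 without mutant replicate 2, control atrium replicate 1 and control atrium replicate 3, and 0.0311 with array weights), among them the repressor Nr1d1 by -0.56 ± 0.10 and Clock by -0.43 ± 0.09. Gja1, the main ventricular connexin, was at 13.56 ± 0.12 in mutant atria, 13.64 ± 0.06 in control atria and 13.72 ± 0.07 in ventricles. With the mean of all probe sets Gja1 was higher in ventricles than in control atria (0.24, adjusted p = 0.0274) and lower in mutant atria than in ventricles (-0.28, adjusted p = 0.0232), the latter also with the Y-linked covariate (-0.28, adjusted p = 0.0316). With the hepatocyte covariate Gjc1, Cpne5, Sfrp5, Axin2 and Cidea still passed in mutant against control atria, and the other genes of these 2 paragraphs did not.

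The sex-linked transcripts were alike in the 3 ventricles, which mutant replicate 1 resembled, and were mixed within both atrial groups. Xist stood at 12.48, 6.73 and 6.48 in the mutant atria, 12.73, 8.55 and 10.91 in the control atria and 11.84, 11.87 and 11.80 in the ventricles, and the Y-linked Eif2s3y at 3.90, 10.01 and 10.05, at 6.35, 9.97 and 9.53, and at 3.82, 3.70 and 3.67. Eif2s3y differed between ventricles and control atria by -4.89 ± 1.52 (adjusted p = 0.0229), and did not pass without control atrium replicate 2 (0.0792) or 3 (0.0642) or any of the ventricles (0.0538 to 0.0554), with an intensity trend (0.0667) or with the hepatocyte covariate (0.128). Single control atrium arrays carried the signal of both sexes, as replicate 3 did with Xist at 10.91 and Eif2s3y at 9.53, and the labels do not say whether a sample came from a single animal. The deviations of mutant and control atria with the same replicate number from their group means correlated across genes at 0.125, 0.051 and 0.023, and those of mutant replicate 3 and control atrium replicate 2 at 0.145. Of the 10 splits of the 6 arrays in each comparison, 1, the real one, gave as many genes (3192, 9615 and 5956 in all 9 arrays), and the highest of the others gave 0. Each other split mixes the groups compared, so their difference enters the spread and calls could hardly arise. With 10 splits the share cannot be under 0.05, so these counts decide nothing about chance.

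Many ventricular-enriched genes rose in the mutant right atria, 263 of the 420 at least 2-fold higher in the ventricle. The sex of the animals does not account for it, since the shift of the ventricular list was 1.377 ± 0.0777 with the Y-linked covariate against 1.365 without. Ventricular tissue in the mutant samples may contribute: over 88 genes higher in the ventricle by a log2 ratio of at least 2, the median implied share was 25.2% (quartiles 8.26% and 49%), and 5.68% fell short of the rise this predicts by the wide margin set for the first test. Admixture would raise all 88 genes by one share, so the median is not an estimate of its amount. At 25.2% Lrtm1 would rise by 2.62, but it differed by -0.25 ± 0.12. Irx4 would rise by 2.26 and rose by 0.98 ± 0.24. A single share as the whole cause was argued against by the second test, in which 52.3% departed from the predicted change, 20 above and 26 below, against 1.18% in simulated mixtures, and by 5 genes above the ventricle itself, among them Irx3 and Myh7. Some admixture stays open, as does a response of the mutant atrium itself.

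Hepatocyte transcripts were found in the control right atria. Shares were taken over the 29 listed genes not looked at before with a level above 6 in a control array. For these, replicates 2 and 3 held a median of 43.5% and 4.78% of the signal of replicate 1. For replicate 3 the quartiles were 0.488% and 12.9%. Of 52 listed genes 47 were measured, 33 were higher in control atria than in ventricles, and the abundant Alb averaged 10.60 ± 1.77 against 5.14 ± 0.20. For the same 29 genes, expression by the atrial tissue itself is argued against by the spread between control arrays. Its median lay at the 99.4th percentile of genes of like level. The 29 were picked by their highest control array, which favours a wide spread, and the genes of like level were not. Single listed genes can differ from this reading. Ahsg stood at 9.39, 9.38 and 9.24 in control atria, 8.74, 8.48 and 8.21 in mutant atria and 5.43, 5.50 and 5.72 in ventricles. Liver RNA in the control samples is the candidate explanation that remains: of the 29 genes not looked at before with a level above 6 in a control array, 27 (93.1%) kept the order of the control replicates, against 21.4% of all genes above 6. It would concern the 39 of the 242 genes at least 2-fold lower in mutant atria that follow this order with a gap of 1.5, while Hamp, with 12.45 ± 0.16 in the control atria, does not follow it.

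Mesothelial markers fell together in the mutant right atria, in 13 of 13 cases. Mesothelium brought along with liver tissue is argued against, since the markers differed between control replicates 1 and 3 by a median of 0.167 ± 0.0601, against 2.3 for the hepatocyte list. This error is taken over the 13 markers in a single pair of arrays and measures no spread between samples. The falls were not equal and ran from -0.676 to -2.02, with an interquartile range of 0.707. That interquartile range lies within the limit set beforehand, so less mesothelium in the mutant samples stays a candidate. Dissection and the mutation both stay open behind it, and a lower level per cell was not tested.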
